A study of Homo sapiens with 43 samples.

How the data were processed

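The series profiled RNA bound by proteins with eCLIP (enhanced crosslinking and immunoprecipitation) in HEK293T cells, a human embryonic kidney line. Per the labels' protocols, cells were crosslinked with ultraviolet light, the RNA was cut by limited RNase I digestion, and the RNA-binding protein (RBP) was immunoprecipitated. Complexes were then run on a protein gel, a region spanning 75 kDa above the protein was cut out, and the RNA in it was sequenced. The series title describes tags integrated by CRISPR/Cas9 into the genes of the RBPs, so that an antibody against the tag can replace an antibody against the protein.

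The 43 samples comprised 25 immunoprecipitation libraries with peak lists and 18 input samples, whose own files were not used here. The inputs entered only through the authors' normalisation. Of the 25 libraries, 11 came from RBPs. The 5 libraries called wild type here used antibodies against HNRNPC, FMR1, RBFOX2, LIN28 or DGCR8 in wild-type cells. The 6 tagged libraries were V5 libraries of HNRNPC isoform 1, HNRNPC isoform 2, RBFOX2 and LIN28, and FLAG libraries of FMR1 and DGCR8. A further 14 libraries, called FLAG-only and V5-only in the labels, were cut from 7 gel ranges of 75 kDa each. Successive ranges began 25 kDa apart, so neighbouring ranges shared 50 kDa. The 7 inputs of the gel ranges were labelled by range without an antibody, against 2 immunoprecipitations per range. Each RBP and tag state had 1 library, and each tag had 1 library per range.

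Each deposited peak list gave a position, a strand and 2 values per peak, without a header. The authors' −log10 p per peak ran from 0 to a cap of 400, with a further 3171 significant peaks, many of high fold, at a lower ceiling of 15.7, and the authors' log2 fold per peak compared the immunoprecipitation with its size-matched input. Both are the authors' own values for the peak and were used here only to describe, rank or filter peaks within a list. Peaks with a negative fold carried a −log10 p of 0 in all 25 lists, and no peaks of a list overlapped each other on the same strand. Positions are in the human build hg19, per the submitters' processing notes, and are given 1-based. Those notes also name cutadapt, STAR, GATK, Picard and SAMtools without versions. The peak caller is not given in the sources used here. Every library had its own list, so peaks had been called per library and not on pooled libraries.

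Peaks with a −log10 p of at least 3 and a log2 fold of at least 3 (8-fold over input) were called significant, a threshold usual for this assay and not taken from the labels. Lists were compared by overlap of at least 1 nt on the same strand. Shares of peaks carry 95% Wilson intervals. They cover counting error over peaks only, and neighbouring peaks are not independent. No read totals were used, so the depth of each library is unknown in reads. The folds of a library fell on steps that ratios of whole read numbers would give. With the commonest fold taken as 3 reads over an input of 1 read, between 34.8% and 71.1% of peaks lay on a whole multiple (relative tolerance 0.0001), against at most 0.0205% for a shifted step. Peaks at the commonest fold lie on a whole multiple by construction, and a commonest fold of 1 read would give whole multiples as well. These shares therefore do not show that it stood for 3 reads in each library. Under that unchecked assumption, the step estimates the log2 ratio of input depth to immunoprecipitation depth. It ran from −1.27 in HNRNPC wild type to 1.68 in DGCR8 FLAG. At an input of 1 read, an 8-fold enrichment then needed 20 reads in HNRNPC wild type and 3 in DGCR8 FLAG. A site of the same occupancy could therefore be called in some libraries and missed in others.

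Tests were fixed before the data were examined. The pairing of the 5 wild-type with the 5 tagged libraries (isoform 1 for HNRNPC) was tested by an exact permutation over the 120 pairings, one-sided. Overlap of tagged libraries with same-antibody tag-only sites was tested by exact permutation of the tag labels over the 6 tagged libraries, one-sided. Numbers of significant peaks in FLAG-only and V5-only libraries were compared by a two-sided exact sign-flip permutation test over the 7 gel ranges, and the pairing of ranges between antibodies by an exact permutation over 5040 pairings, one-sided. Benjamini-Hochberg adjustment covered these 4 tests. The gel ranges overlap one another and nothing in the labels says that libraries came from separate cultures. The sign-flip p-value therefore measures a spread between these libraries, which may be technical. The other p-values only rank the real arrangement among all arrangements of single libraries. Libraries of 1 sample per group were compared without a p-value.

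Alternatives fixed in advance were a stricter threshold (−log10 p of at least 5), a looser one (log2 fold of at least 2), an overlap of at least 50% of both peaks, the 1000 significant peaks of highest fold per library, the share of tagged instead of wild-type peaks, HNRNPC isoform 2 in place of isoform 1, removal of peaks at tag-only sites, the share of called peaks that was significant, an unpaired permutation and leaving out each RBP. A distance of up to 1 kb in place of overlap, leaving out each gel range and, for the matched ranges, a −log10 p of at least 15 or 20 were added after the data had been seen.

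An annotation and sequence of build hg19 were not used here. Motif, intron, coding-sequence, microRNA hairpin and gene list shares, which had been planned, were therefore not computed, and regions are named by position without a gene or feature. Named regions were, for each RBP, the 3 significant wild-type peaks with the highest lowest fold over all libraries of that RBP, among peaks overlapped by a significant peak in every library of the RBP and by none in the tag-only libraries of the antibody used for its tag. For the tag-only libraries they were the 3 regions significant in the most libraries.

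Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap step was tested on simulated lists of 2000 peaks with a planted share of 30%. It recovered 30.03% and counted the same 600 overlaps as bedtools 2.31.1. On simulated values without a difference the sign-flip test called 97 of 2000 sets of 7 ranges, and it called 1969 of 2000 sets with a mean of 2 SD. The pairing test called 70 of 2000 unrelated matrices.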

Results

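eCLIP peak lists were examined for 5 RBPs of HEK293T cells, each immunoprecipitated with an antibody against the protein and, from tagged cells, with an antibody against V5 or FLAG. The RBPs were HNRNPC, a nuclear protein that binds uridine-rich stretches of nascent transcripts, FMR1, the translational regulator lost in fragile X syndrome, and RBFOX2, a splicing regulator. They also included LIN28, which binds microRNA precursors and messenger RNAs, and DGCR8, the RNA-binding partner of the nuclease DROSHA in microRNA processing. The labels do not say which LIN28 paralog was profiled. A further 14 libraries, named FLAG-only and V5-only without an RBP, came from 7 gel ranges between 25 and 250 kDa. The lists held between 25723 and 100860 called peaks per library. Each RBP and tag state had 1 library, so values for a single RBP have no replicate error and carry counting intervals only.

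The number of RNA sites enriched over input differed widely between RBPs and between antibodies for the same RBP. FMR1 FLAG had the most significant peaks, 17354, against 3072 in FMR1 wild type, a ratio of 5.65. LIN28 V5 had 7780 against 2020 in LIN28 wild type, a ratio of 3.85. For the remaining RBPs the tagged library gave fewer sites. RBFOX2 had 1900 in V5 and 3049 in wild type, DGCR8 had 457 in FLAG and 1375 in wild type, and HNRNPC had 375 in V5 isoform 1, 1168 in V5 isoform 2 and 1357 in wild type. Over the 25 libraries the median was 1915 significant peaks, which was between 0.555% and 22.1% of the peaks called in a library. HNRNPC and DGCR8 FLAG had the lowest shares among RBP libraries, with 0.760% of HNRNPC V5 isoform 1 peaks, 1.78% of DGCR8 FLAG peaks, 1.97% of HNRNPC V5 isoform 2 peaks and 2.15% of HNRNPC wild-type peaks significant. DGCR8 FLAG had the highest estimated log2 ratio of input to immunoprecipitation depth, 1.68. The 3 HNRNPC libraries had the lowest, with log2 values of −1.27 in wild type, −0.89 in isoform 1 and −0.98 in isoform 2. With the commonest fold taken as 3 reads, an 8-fold enrichment at an input of 1 read then needed 15 to 20 reads. At a −log10 p of at least 5 the median number fell to 1177, and at a log2 fold of at least 2 it rose to 5244.

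Whether a tag antibody recovers the sites seen with an antibody against the protein was examined by overlap. LIN28 and FMR1 sites were recovered most completely with lists at full length, although for FMR1 this did not hold in lists of at most 1000 peaks, where its share was 12.8%. Of the 2020 significant LIN28 wild-type peaks, 81.8% (95% Wilson interval 80.0% to 83.4%) overlapped a significant LIN28 V5 peak, and of the 3072 FMR1 wild-type peaks 67.3% (65.6% to 68.9%) overlapped an FMR1 FLAG peak. The share was 29.6% (28.1% to 31.3%) for RBFOX2, 18.9% (16.9% to 21.1%) for DGCR8 and 6.71% (5.49% to 8.16%) for HNRNPC with V5 isoform 1. With V5 isoform 2 the HNRNPC share was 11.3% (9.70% to 13.1%).

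In each of the 5 RBPs the own tagged library was overlapped far more often than the tagged library of any other RBP. The mean over the RBPs was 40.9% for the own library and 1.53% for the libraries of other RBPs. The real pairing gave the highest mean of all 120 pairings (exact permutation p = 0.00833, one-sided, the smallest p this design allows, n = 5 RBPs, adjusted p = 0.0167 over 4 tests). The highest overlap with a tagged library of another RBP was 0.884% for HNRNPC, 7.58% for FMR1, 1.41% for RBFOX2, 13.4% for LIN28 and 1.02% for DGCR8. Against single tag-only libraries the overlap reached 19.2% for FMR1, 6.93% for LIN28, 4.64% for HNRNPC, 1.31% for DGCR8 and 0.590% for RBFOX2. The HNRNPC value came from V5-only at 125 to 200 kDa, and the next highest was 2.43%, against own-library shares of 6.71% with isoform 1 and 11.3% with isoform 2. Wild-type peaks that were not significant overlapped the own tagged list much less often, from 0.199% in DGCR8 to 11.3% in FMR1.

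**Figure D1:**
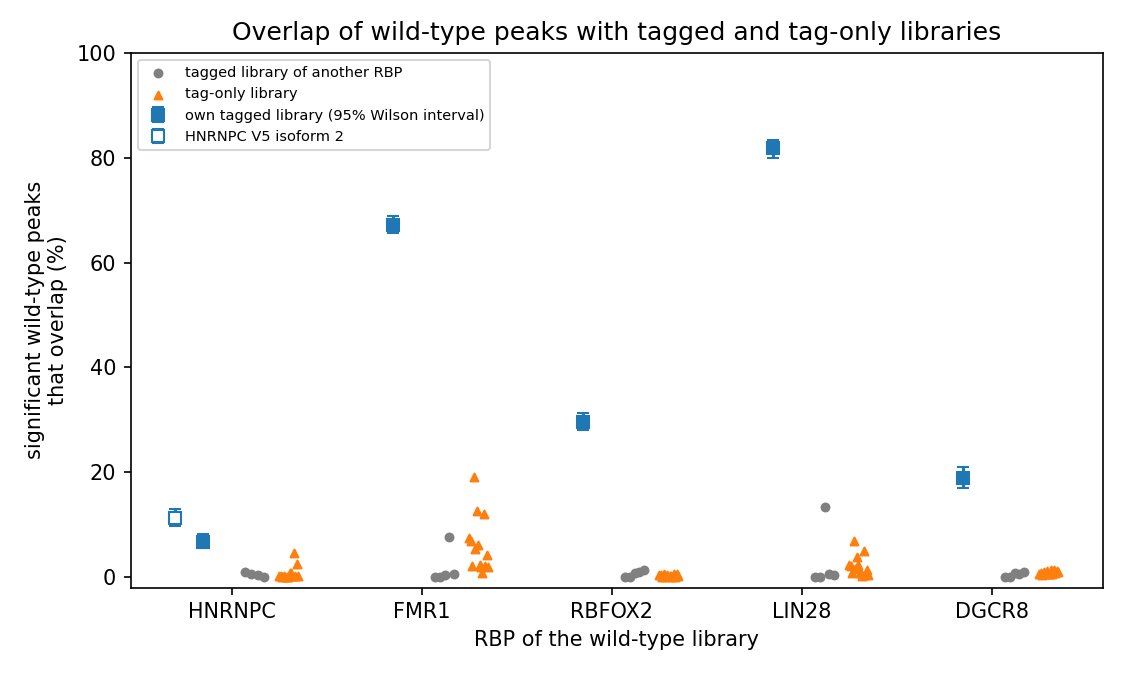
Share of significant wild-type peaks (y axis, percent) that overlap a significant peak of the own tagged library (squares with 95% Wilson intervals), of tagged libraries of other RBPs (grey circles) and of the 14 tag-only libraries (orange triangles), by RBP. The own library lies highest in each RBP, from 6.71% for HNRNPC isoform 1 to 81.8% for LIN28.

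The direction of the comparison changed which RBP ranked highest. Of RBFOX2 V5 peaks 46.6% (44.4% to 48.9%) and of DGCR8 FLAG peaks 46.2% (41.7% to 50.8%) overlapped a significant wild-type peak of the same RBP. The share was 28.8% (27.8% to 29.8%) for LIN28 V5, 22.7% (18.7% to 27.2%) for HNRNPC V5 isoform 1 and 13.2% (12.7% to 13.7%) for FMR1 FLAG. The lists of FMR1 FLAG and LIN28 V5 were the longest among the RBPs. With at most 1000 peaks of highest fold per library the share of wild-type peaks was 42.3% for LIN28, 31.2% for RBFOX2, 24.9% for DGCR8, 12.8% for FMR1 and 7.20% for HNRNPC, so that FMR1 fell below RBFOX2 and DGCR8. That cut was unequal. It left the 457 peaks of DGCR8 FLAG and the 375 of HNRNPC V5 isoform 1 whole, but took FMR1 FLAG down from 17354. The change of rank may therefore reflect the trimming. With lists at full length, the share of wild-type peaks within a distance of 1 kb rose to 40.7% for DGCR8, 50.4% for RBFOX2 and 12.9% for HNRNPC. At the looser threshold the HNRNPC share was 18.0%, and with 50% of both peaks shared the DGCR8 share was 11.3%.

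Sites in the strongest class of wild-type enrichment were recovered most often in each RBP. For DGCR8 the share overlapped by the own tagged library was 3.42% (2.12% to 5.48%) among 468 peaks with a log2 fold from 3 to under 4, and 45.0% (40.5% to 49.4%) among 476 peaks with a log2 fold of 5 and above. RBFOX2 went from 19.9% (18.0% to 21.9%) to 65.7% (60.6% to 70.5%) and LIN28 from 75.6% (72.9% to 78.0%) to 99.2% (97.1% to 99.8%) between the same classes. FMR1 stood at 66.8% and 66.5% in the lower classes and at 91.5% (82.8% to 96.1%) among its 71 strongest peaks. HNRNPC went from 5.98% (4.70% to 7.58%) to 20.6% (10.3% to 36.8%), the latter over only 34 peaks.

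**Figure D2:**
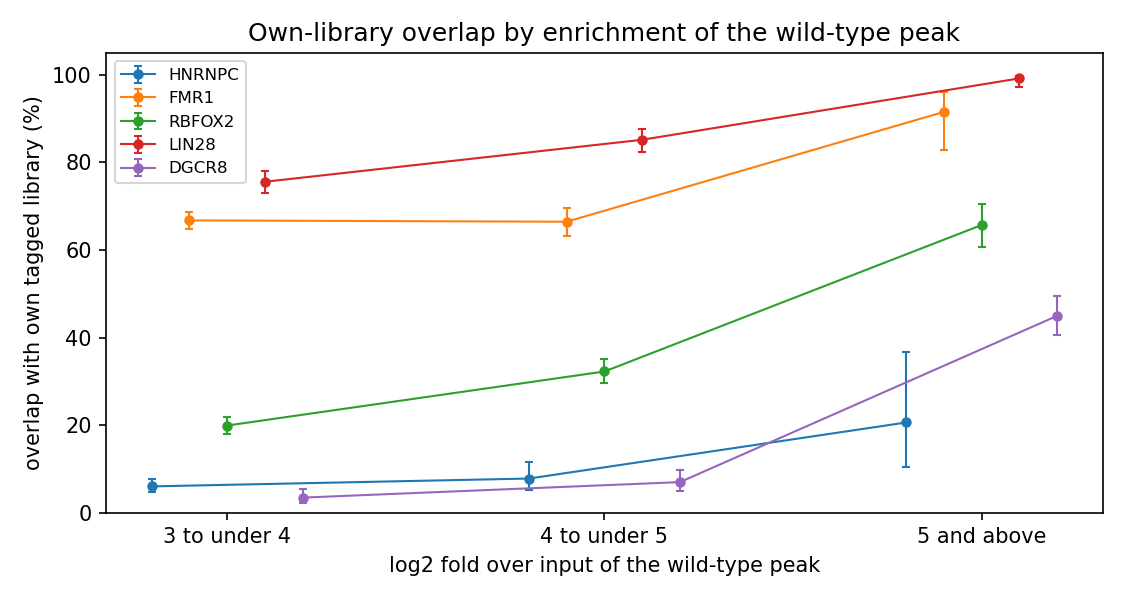
Share of significant wild-type peaks that overlap the own tagged library (y axis, percent, bars show 95% Wilson intervals) in 3 classes of the wild-type peak's log2 fold over input (x axis), with 1 line per RBP and isoform 1 for HNRNPC. The DGCR8 share is 3.42% in the lowest class and 45.0% in the highest.

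The enrichment within the tagged lists followed the wild-type sites as well. In DGCR8 FLAG the median log2 fold was 3.86 at the 369 peaks lying on significant DGCR8 wild-type peaks, 0.90 at the 4678 peaks lying on other wild-type peaks and 2.09 where no wild-type peak had been called. The corresponding medians were 4.40, 1.97 and 1.40 in LIN28 V5, 3.74, 2.08 and 2.02 in FMR1 FLAG, 3.0, 1.0 and 1.30 in RBFOX2 V5, and 1.95, 1.11 and 0.92 in HNRNPC V5 isoform 1. The HNRNPC median at wild-type sites was thus below the threshold of 3.

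The named sites shared by both antibodies lay side by side at a single place for DGCR8, LIN28 and RBFOX2. All 3 named DGCR8 regions fell on the plus strand of chromosome 13, at positions 92003597 to 92003616, 92003617 to 92003622 and 92003627 to 92003636, with log2 folds of 11.74, 11.70 and 11.57 in wild type. The overlapping DGCR8 FLAG peaks had log2 folds of 7.91, 7.91 and 8.81, the lower value belonging to a single peak that overlapped both of the former. The 3 LIN28 regions lay on the minus strand of chromosome 11, at 17098715 to 17098716, 17098717 to 17098741 and 17098742 to 17098748, with log2 folds of 9.71, 9.75 and 9.60 in wild type and of 10.20, 10.20 and 10.03 in V5. The value of 10.20 belonged to a single V5 peak, at 17098715 to 17098718. The 3 RBFOX2 regions adjoined one another on the plus strand of chromosome 1, at 227955353 to 227955491, 227955492 to 227955534 and 227955535 to 227955572, with log2 folds of 7.49, 7.08 and 6.93 in wild type and a single V5 peak at 7.01.

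FMR1 and HNRNPC regions were less strongly enriched. FMR1 regions lay on the minus strand of chromosome 1 at 115259862 to 115259880 and 115259881 to 115259896 and on the plus strand of chromosome X at 41057914 to 41057944. Their log2 folds were 5.86, 5.27 and 5.40 in wild type and 5.92, 6.90 and 5.30 in FLAG. Only 31 HNRNPC wild-type peaks were significant in all 3 HNRNPC libraries. The named ones were neighbours on the minus strand of chromosome 10, at 5240943 to 5240966 and 5240967 to 5240992, and a site on the plus strand of chromosome 5 at 149402570 to 149402618. The neighbours had log2 folds of 5.07 in wild type, 4.24 in isoform 1 and 4.31 in isoform 2, and the site on chromosome 5 had 3.94, 3.97 and 4.15. A single isoform 1 peak overlapped both neighbours. The site on chromosome 5 missed the stricter threshold, with a −log10 p of 4.20 in isoform 1.

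The tagged HNRNPC isoforms shared few sites with each other. Of the 375 significant isoform 1 peaks, 18.4% (14.8% to 22.6%) overlapped an isoform 2 peak, and 22.7% (18.7% to 27.2%) overlapped a wild-type peak. Of the 1168 isoform 2 peaks, 6.25% (5.00% to 7.79%) overlapped isoform 1 and 13.1% (11.3% to 15.2%) overlapped wild type. The difference between these shares was not tested. At the looser threshold 43.3% of isoform 1 peaks overlapped isoform 2.

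The tag-only libraries name a tag and no RBP, and the labels do not say whether their cells expressed a tag, so their peaks are called background here in that sense only. Each of the 14 libraries had significant peaks, from 383 in V5-only at 25 to 100 kDa to 11119 in FLAG-only at 125 to 200 kDa. The FLAG antibody gave more sites than the V5 antibody in 7 of 7 gel ranges, with a mean log2 ratio of 1.51 ± 0.46 (SD, n = 7 ranges), or 2.86-fold, and ratios between 1.69 and 4.33 (two-sided exact sign-flip permutation p = 0.0156, the smallest this design allows, adjusted p = 0.0208). Both antibodies peaked at 125 to 200 kDa, where V5-only had 6562 significant peaks, and both had the fewest at 25 to 100 kDa, where FLAG-only had 865. The estimated ratio of input to immunoprecipitation depth was also higher in FLAG-only than in V5-only in 6 of the 7 ranges. In the range of 175 to 250 kDa it was lower, with log2 values of 0.25 and 0.50, and FLAG-only had 3889 significant peaks there against 899. That range has 1 library per antibody, and what depth contributes to the numbers of peaks was not tested.

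**Figure D3:**
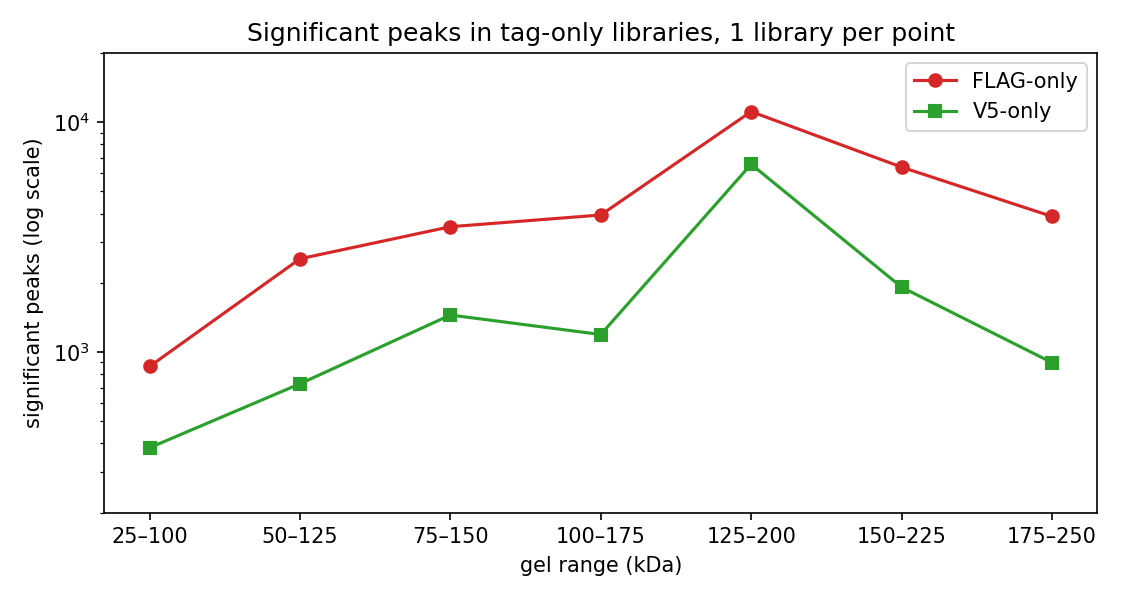
Number of significant peaks (log scale) in FLAG-only and V5-only libraries by gel range in kDa, with 1 library per point. FLAG-only lies above V5-only in 7 of 7 ranges, and both are highest at 125 to 200 kDa, with 11119 and 6562 peaks.

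Over all significant peaks, background sites were shared between the antibodies more often within a gel range than between ranges. On average 15.2% of FLAG-only peaks overlapped a V5-only peak of the same range and 6.93% overlapped a V5-only peak of another range. The real pairing gave the highest mean of 5040 pairings (exact permutation p = 0.000198, one-sided, the smallest this design allows, n = 7 ranges, adjusted p = 0.000794). The matched share was 32.5% at 125 to 200 kDa and between 9.32% and 14.7% in the other ranges. It was the highest of the 7 V5-only libraries in only 1 range, since the long V5-only list at 125 to 200 kDa was overlapped most by the rest. At the looser threshold the matched mean was 29.8%, and among peaks with a −log10 p of at least 20 the call was lost, with 15.8% in the same range and 15.5% in other ranges (exact permutation p = 0.474, n = 7).

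A few background regions recurred throughout. Of 24715 regions significant in at least 1 tag-only library, 8815 were significant in at least 2, 300 in at least 7 and 3 in all 14. The latter lay on chromosome 1 at 237766446 to 237766534 on the plus strand, on chromosome 2 at 230045573 to 230045740 on the minus strand, and on chromosome 1 at 91853042 to 91853160 on the minus strand. Their log2 folds were 5.32 ± 0.88, 4.72 ± 0.91 and 3.90 ± 0.64 (SD, n = 14 libraries). They were also significant in 3, 1 and 3 of the 11 RBP libraries.

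Tag-only sites made up very different shares of the RBP lists. FMR1 stood highest, with 37.9% (36.2% to 39.6%) of significant wild-type peaks and 27.0% (26.4% to 27.7%) of FLAG peaks at a significant tag-only site, although the wild-type library used no tag antibody. These shares exceeded those of the FMR1 peaks that were not significant, 16.8% and 13.3%. LIN28 had 14.1% in wild type and 16.6% in V5, where peaks that were not significant had 14.6% and 11.3%. DGCR8 had 4.80% in wild type and 12.3% in FLAG, against 13.7% and 12.6% of peaks that were not significant. RBFOX2 had 2.03% (1.59% to 2.60%) in wild type and 3.0% (2.32% to 3.87%) in V5, below the 7.04% and 10.2% of its peaks that were not significant. In HNRNPC 7.07% of wild-type, 4.0% of isoform 1 and 2.48% of isoform 2 peaks lay at tag-only sites, against 1.41%, 1.99% and 1.63% of those that were not significant. Removing all peaks at tag-only sites left the own-library overlap at 61.8% for FMR1 and moved the other RBPs within their intervals.

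Tagged libraries were not shown to carry more background of their own antibody. The share of peaks at same-antibody tag-only sites minus the share at sites of the other antibody averaged 2.40 percentage points over the 6 tagged libraries (exact permutation p = 0.133, 2 of 15 label arrangements as large, the smallest p possible being 0.0667, one-sided, adjusted p = 0.133). It was 12.1 points in FMR1 FLAG, 3.28 in DGCR8 FLAG, 3.73 in HNRNPC V5 isoform 1, 2.48 in HNRNPC V5 isoform 2, −0.32 in RBFOX2 V5 and −6.85 in LIN28 V5. FLAG-only libraries held 32244 significant peaks in total and V5-only libraries 13125. The longer FLAG-only lists by themselves raise this difference in FLAG libraries and lower it in V5 libraries. The single values and their mean therefore include an effect of list length. Wild-type libraries, which used no tag antibody, differed as well, with FLAG-only minus V5-only at 14.5 points in FMR1 and 4.85 in LIN28 and V5-only minus FLAG-only at 6.78 points in HNRNPC. This design cannot reach a p under 0.05. With at most 1000 peaks per library the mean was 0.649 points.

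**Figure D4:**
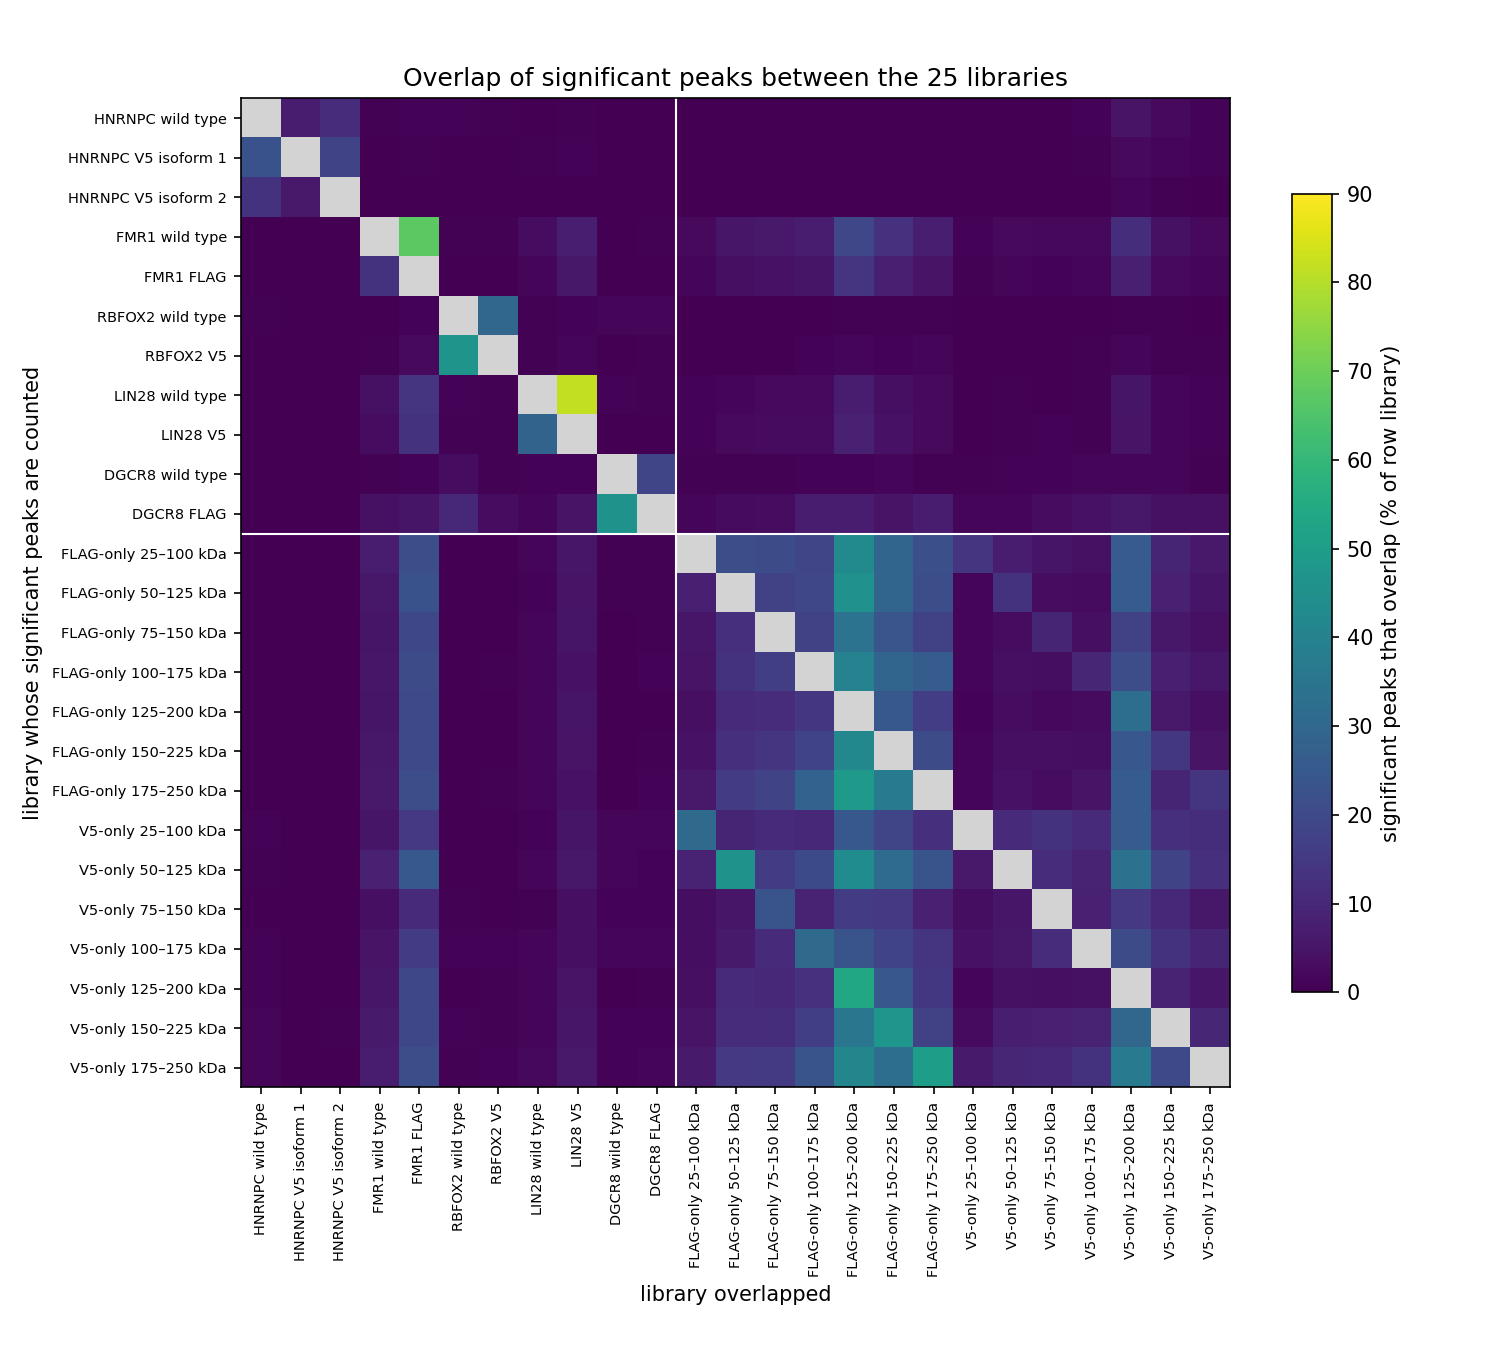
Share of the significant peaks of each library (rows) that overlap a significant peak of another library (columns), as a percentage shown by colour, for the 25 libraries, with the own library in grey. White lines separate the 11 RBP libraries from the 14 tag-only libraries, and the brightest cell is LIN28 wild type in LIN28 V5, at 81.8%, and among tag-only libraries V5-only in FLAG-only at 125 to 200 kDa, at 53.8%.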

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

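The tests of a shared input and of the depth ratio in V5-only libraries, the cut at a −log10 p of 15 and the sign-flip tests of HNRNPC sites, with and without a gel range, were chosen only after the results had been seen.

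The V5-only library at 125 to 200 kDa stood apart from the other V5-only libraries. It had 6562 significant peaks where the next had 1915, and 11.5% of its called peaks were significant where the next had 3.10%. Of the gaps between successive significant peaks of a strand, 28.6% were under 1 kb where the next library had 16.6%. The matched overlap of the FLAG-only library of that range, 32.5%, also stood apart from the next value of 14.7%. Of 16 sets of 7 values examined this way, 4 had a value far from the rest, where chance gives about 1 in 20, or 0.8 sets. These 4 values all came from the range of 125 to 200 kDa and are not independent. The excess over 0.8 therefore says nothing beyond that range. The tagged library had more significant peaks than wild type for FMR1, with a ratio of 5.65, and for LIN28, with 3.85, and fewer for HNRNPC, with 0.276, RBFOX2, with 0.623, and DGCR8, with 0.332. This difference in direction between RBPs was not tested, since each rests on 1 library per state.

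FLAG-only and V5-only libraries of the same gel range shared more sites than libraries of different ranges, with a ratio of matched to unmatched overlap of 2.19. That ratio came from lists of unequal length. In lists of the 383 significant peaks of highest fold, the matched mean was 16.6% and the unmatched mean 3.49%. Counting noise of an input read shallowly and used for both antibodies may contribute but stayed open. The ratio was 1.02 among peaks with a −log10 p of at least 20 (0.911 to 1.33 on leaving out each range, as few as 6 peaks in a list), a cut that drops 581 peaks at the lower ceiling, and 1.27 (1.19 to 1.36) at a cut of 15, which keeps them. With only the FLAG-only peaks split by −log10 p, a split chosen afterwards, the ratio fell with strength. It was 2.37 from 3 to under 5, 2.32 from 5 to under 10, 1.84 from 10 to under 20 and 1.24 from 20 (2478 peaks). That the RNA recovered depends on the gel range stayed open, since same-antibody libraries did not clearly share fewer sites with distance in kDa (mean Spearman's rho −0.15 over pairs of libraries, exact permutation p = 0.244, n = 7 ranges, lists of 383 peaks). A bias of a shared input, which the labels do not state, stayed open too. Matched overlap of different antibodies exceeded same-antibody overlap at neighbouring ranges in only 4 of 7 ranges, with a median ratio of 1.06 (0.729 to 2.37).

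DGCR8 FLAG peaks lay at RBFOX2 wild-type sites in 46 of 457 cases, 10.1% (7.63% to 13.2%), against a median of 0.352% over the 96 pairs of libraries of different RBPs. That median includes pairs with HNRNPC libraries, which reached at most 0.884%. Of DGCR8 FLAG peaks, 5.03% overlapped FMR1 FLAG, 4.60% LIN28 V5, 3.94% FMR1 wild type and 2.84% RBFOX2 V5. In reverse, 1.41% of RBFOX2 wild-type peaks overlapped DGCR8 FLAG, and 2.98% of DGCR8 wild-type peaks overlapped RBFOX2 wild type. Background at significant tag-only sites was argued against, since the share at RBFOX2 wild-type sites was 9.48% (6.98% to 12.7%) once peaks at those tag-only sites were left out. Tag-only sites below the threshold were not left out, so background at weaker sites stayed open. Carry-over of reads from the RBFOX2 wild-type library stayed open, as the shared sites had a median percentile of −log10 p of 72.5 in that library (bootstrap interval 53.9 to 77.2), a measure blunted by the lower ceiling. Sites bound by both proteins stayed open as well, with 6.52% of the shared peaks (2.24% to 17.5%, 3 of 46) also significant in both DGCR8 wild type and RBFOX2 V5. Of the 46 peaks, 16 were significant in DGCR8 wild type and 9 in RBFOX2 V5, and they formed 26 clusters.

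HNRNPC wild-type sites were met in V5-only libraries more often than in FLAG-only libraries in 7 of 7 gel ranges, at 1.33% ± 1.65 against 0.0737% ± 0.0737 of the sites (SD, n = 7, exact sign-flip permutation p = 0.0156, adjusted p = 0.026 over 5 RBPs), and as a share of tag-only peaks at 0.819% against 0.0207%. Without the range of 125 to 200 kDa, whose V5-only library met the most sites, the former means were 0.774% and 0.0614% (exact sign-flip permutation p = 0.0312, n = 6). A lower depth ratio in V5-only libraries stayed open, since only 1 range had a higher ratio in V5-only, with 1 library per antibody. The V5-only share was still higher there, by 1.06 percentage points. It was 10 of 899 peaks (0.605% to 2.04%) against 2 of 3889 in FLAG-only (0.0141% to 0.187%). Carry-over of reads from the HNRNPC wild-type library may contribute and stayed open, with a median percentile of −log10 p of 80.9 (bootstrap interval 66.7 to 84.4) for the 95 HNRNPC sites concerned, blunted in the same way. RNA bound by HNRNPC and brought down with the V5 antibody stayed open too, as 18.9% of those sites (12.3% to 28.0%) were also significant in an HNRNPC V5 library, against 15.5% (13.6% to 17.6%) of the remaining wild-type sites.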

How the results depend on the processing

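The overlap within 1 kb, the omission of single gel ranges and the higher cuts on −log10 p were chosen only after the data had been seen. The own-library pairing was the highest of all pairings under each alternative run, with means from 23.7% to 55.5%, and on leaving out each RBP from 30.6% to 49.4% (exact permutation p = 0.0417). FLAG-only exceeded V5-only under each alternative, with mean log2 ratios from 1.03 to 1.74 and exact permutation p up to 0.039, and on leaving out each range from 1.41 to 1.64 (p = 0.0312). The matched-range overlap passed its test under the alternatives fixed in advance, from 10.99% to 29.8%, on leaving out each range, and at a −log10 p of at least 15 (16.3%, exact permutation p = 0.0274). At a −log10 p of at least 20 it did not, with 15.8% matched and 15.5% unmatched (exact permutation p = 0.474), on lists of as few as 6 peaks. The same-antibody difference did not pass its exact permutation test, with p from 0.0667 to 0.2 in a design that cannot go lower than the former.

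Sizes depended more on the processing, and the cause was not tested unless given. The median number of significant peaks was 1177 at the stricter and 5244 at the looser threshold, by construction. Own-library overlap at the stricter threshold was 77.4% for FMR1, 34.6% for RBFOX2, 92.4% for LIN28 and 23.9% for DGCR8, and at the looser threshold 18.0% for HNRNPC, 81.1%, 36.8%, 86.8% and 15.7%. With 50% of both peaks shared it was 51.7% for FMR1, 23.1%, 69.6% and 11.3%, and within 1 kb 12.9% for HNRNPC, 87.3%, 50.4%, 86.3% and 40.7%, again by construction. With at most 1000 peaks per library it was 12.8% for FMR1, 42.3% for LIN28 and 24.9% for DGCR8. As a share of tagged peaks it was 22.7% for HNRNPC, 13.2%, 46.6%, 28.8% and 46.2%. It was 11.3% for HNRNPC with isoform 2 and 61.8% for FMR1 without tag-only sites. Isoform 1 peaks at isoform 2 peaks rose to 43.3% at the looser threshold. Read totals were not used, so what depth limits was not tested. The inferred number of reads needed for an 8-fold enrichment was highest in HNRNPC wild type, at 20. Alternatives for motif, region and gene list shares were not run, since those shares were not computed.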

Other observations

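The regions and comparisons in this part were chosen only after the values had been seen, and no explanation is offered for them. With neighbouring peaks within 1 kb counted as a single site, further sites shared by both antibodies of an RBP followed those named by rule. For DGCR8 they included chromosome 20 at 3898169 to 3898211 on the plus strand, with log2 folds of 8.73 in wild type and 7.68 in FLAG, and chromosome 8 at 135817125 to 135817147 on the minus strand, with 6.97 and 6.48. For LIN28 they included chromosome 11 at 17097137 to 17097170 on the minus strand, with 9.54 in wild type and 10.48 in V5, and chromosome 16 at 1878212 to 1878249 on the plus strand, with 8.46 and 7.58. RBFOX2 shared chromosome 5 at 139646628 to 139646695 on the minus strand, with 7.31 and 6.58. Significant peaks were most clustered in DGCR8 wild type, where 54.9% of the gaps between successive significant peaks of a strand were under 1 kb. RBFOX2 wild type followed at 49.0% and FMR1 FLAG at 48.4%. Among RBP libraries, significant peaks were least clustered in HNRNPC V5 isoform 1, at 11.2%. The DGCR8 site on chromosome 13 alone had 29 wild-type peaks within 1 kb.

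LIN28 and FMR1 sites overlapped each other. Of LIN28 wild-type peaks 13.4% (12% to 15%) and of LIN28 V5 peaks 13.3% (12.6% to 14.1%) overlapped an FMR1 FLAG peak, the longest list, and 7.58% (6.70% to 8.57%) of FMR1 wild-type peaks overlapped LIN28 V5. Between the wild-type libraries the shares were lower, 4.06% of LIN28 peaks in FMR1 and 2.83% of FMR1 peaks in LIN28. Tag-only libraries, which name no RBP, overlapped the FMR1 FLAG list more often than LIN28 did. The shares were 19.7% to 22.8% in FLAG-only libraries, 24.6% in V5-only at 50 to 125 kDa and 14.9% in V5-only at 25 to 100 kDa. Against LIN28 V5 the FLAG-only libraries stood at 4.36% to 5.43%, below the FMR1 wild-type share.

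For FMR1, LIN28, RBFOX2 and DGCR8, unlike HNRNPC, the comparison of FLAG-only with V5-only libraries at RBP sites depended on whether the share was taken of the sites or of the tag-only peaks. FLAG-only lists were the longer in 7 of 7 ranges. This by itself raises a share of the sites. A test passed only on that share therefore cannot be told apart from list length. A share of the tag-only peaks can fall in a longer list if the added peaks lie elsewhere, but it need not. What list length contributes to a test passed only on the share of tag-only peaks was not tested. Of FMR1 wild-type sites, 8.56% ± 5.63 were met in a FLAG-only library and 3.61% ± 3.82 in a V5-only library (SD, n = 7), and of LIN28 wild-type sites 2.81% ± 2.04 and 1.25% ± 1.69. Both were higher in FLAG-only in each of the 7 ranges (two-sided exact sign-flip permutation p = 0.0156, adjusted p = 0.026 over 5 RBPs). Without the range of 125 to 200 kDa the V5-only means were 2.22% and 0.627%, and the FLAG-only means 6.79% and 2.13% (exact sign-flip permutation p = 0.0312, n = 6). As a share of tag-only peaks neither passed the test, with 5.85% in FLAG-only and 5.86% in V5-only for FMR1 (exact sign-flip permutation p = 1, n = 7) and 1.26% and 1.19% for LIN28 (exact sign-flip permutation p = 0.781, n = 7). For RBFOX2 and DGCR8 the reverse was seen. As a share of tag-only peaks their wild-type sites were higher in V5-only in 7 of 7 ranges, at 0.437% against 0.194% for RBFOX2 and 1.08% against 0.285% for DGCR8 (exact sign-flip permutation p = 0.0156, adjusted p = 0.026). As a share of the sites neither passed, with 0.2999% ± 0.192 in FLAG-only and 0.276% ± 0.213 in V5-only for RBFOX2 (exact sign-flip permutation p = 0.625, n = 7) and 0.748% ± 0.261 and 0.945% ± 0.346 for DGCR8 (exact sign-flip permutation p = 0.0625, n = 7). Summed over ranges, RBFOX2 sites were met 64 times in FLAG-only and 59 times in V5-only libraries, and DGCR8 sites 72 and 91 times.

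Mitochondrial peaks were few. The largest number in a tag-only library was 44 significant peaks, in FLAG-only at 125 to 200 kDa, or 0.396% (0.295% to 0.531%), and the largest share was 0.667% (0.306% to 1.45%, 6 peaks), in V5-only at 175 to 250 kDa. Among RBP libraries DGCR8 FLAG had the most, 4 peaks or 0.875% (0.341% to 2.23%), and 7 of the 11 had none.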
